A study of Mus musculus with 18 samples.

How the data were processed

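Total RNA from small-intestinal crypts of mice aged 2 months was labelled with biotin and hybridised to arrays with 45101 probe sets, per the labels' protocols. The 18 arrays fall into 4 groups, control (n = 4), E2f TKO (n = 5), Myc KO (n = 4) and E2f/Myc QKO (n = 5), taken from the titles, and all 18 columns of values matched a sample, with 0 columns left over. The values are log2 signals deposited by the authors, with the log2 scale inferred from the values, which run from 2.29 to 14.81. The normalization and the probe summary are not given in the sources used here. The values were used as deposited, since the array medians (6.14 to 6.26) differed by 0.126, less than the 0.2 above which quantile normalization would have been applied. Pairs of arrays correlated at 0.973 to 0.996 across probe sets, and 0 pairs had identical values. Scanner files were not analysed here. The labels name no batch, date or sex.

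Probe sets were named from the platform annotation. Of the 45101 probe sets, 64 are controls, 34945 have 1 gene symbol, 932 have several and 9160 have none, and only those with 1 symbol entered the tests of genes. The reference gene table of GRCm38.p6 held the Entrez numbers of 18032 of the 18193 genes, and 0 symbols needed an update. That table gave names and neighbouring genes. A gene was represented by its probe set with the highest mean over the 18 arrays, and 9010 genes had more than 1. No filter on dim probe sets was applied, and no detection calls were used, so a low value is not told apart from background.

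Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in 1 fit of 4 group means to all 18 arrays, two-sided, with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05 on the adjusted p. The 6 comparisons were each of the 3 genotypes against control, QKO against E2f TKO, QKO against Myc KO, and the interaction, which is QKO minus E2f TKO minus Myc KO plus control on the log2 scale. Tables were handled with data.table version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Of 29 gene lists written before the data were examined, 28 had at least 4 measured members and were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The list left out was that of red blood cells. No list call held with the estimated correlation, whose adjusted p is given beside each call. The genes named are those of the targeted loci, the 8 genes raised and the 8 lowered most in each comparison with control among those past the test whose 2 groups of arrays do not overlap, the 5 highest and the 5 lowest past the test in the other comparisons, and up to 4 members with the smallest p of each list described. Groups of 4 and 4 arrays fail to overlap by chance in 2.86% of unchanged genes, and groups of 4 and 5 in 1.59%.

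The alternatives were quantile normalization, only genes above the median level, the mean of a gene's probe sets, probe sets without the _s_at and _x_at suffixes, every probe set tested, a fit of the 2 groups alone, the replicate number as a block, a trended and robust eBayes, array weights, the Xist signal as a covariate since the labels give no sex, controls split into pairs, and leaving out each array in turn. Fits without the arrays labelled E2f TKO 2 and 5, and counts without genes within 20 Mb of a deleted gene, were chosen after seeing the data. Other splits of the samples, at most 100 for each comparison, were counted against the real split. Unchanged groups against the same controls were simulated 100 times for the correlations and covariances between comparisons.

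The scripts were tested on simulated data with the real means and spreads, in which 200 of the 18193 genes were changed by a log2 difference of 0.5, 1 or 2. For E2f TKO against control, 75.8% of the changes of 0.5, 93.7% of those of 1 and 100% of those of 2 were recovered, with 18 false calls among 198. For Myc KO the shares were 59.7%, 91.9% and 100%, with 6 among 172. For QKO they were 68.6%, 93.9% and 100%, with 7 among 181. For the interaction they were 33.8%, 80.6% and 100%, with 9 among 154. A simulated list of 50 genes shifted by -0.3 was recovered, and 0 of 20 unchanged lists were called. Only means and spreads were real, so lists of correlated genes (G1/S at an estimated 0.70) were not tested.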

Results

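RNA from small-intestinal crypts of 18 mice aged 2 months was profiled on 18 arrays. Control mice gave 4 arrays and mice with E2f1, E2f2 and E2f3 deleted (E2f TKO) 5. Mice with Myc deleted (Myc KO) gave 4, and mice with all 4 genes deleted (E2f/Myc QKO, called QKO here) 5. The deletions used Ah-cre, a Cre recombinase under the Cyp1a1 promoter, which ligands of the aryl hydrocarbon receptor switch on. Crypts were taken 2 days after deletion. Whether E2f1 and E2f2 were deleted then or already in the germline is not settled. E2f1 to E2f3 encode transcription factors of the cell cycle, and Myc one of growth and ribosome production. Array medians were 6.14 to 6.19 in control and E2f TKO arrays and 6.22 to 6.26 in Myc KO and QKO arrays. No detection calls were used, so a signal near these medians is not shown to be above background, and a difference from it is at best a lower bound. The number of arrays limits the precision of every value. Differences are on the log2 scale, given with the standard error of the limma fit and an adjusted p (Benjamini-Hochberg).

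The Myc probe set followed the labels in all 18 arrays. Its mean log2 signal was 9.92 ± 0.27 (SD, n = 4) in control crypts, 10.30 ± 0.28 (n = 5) in E2f TKO, 8.24 ± 0.12 (n = 4) in Myc KO and 8.15 ± 0.23 (n = 5) in QKO crypts. Myc fell by 1.68 in Myc KO (limma adjusted p = 3.12e-05) and by 1.76 in QKO (adjusted p = 9.19e-07). The E2f3 probe set with the higher signal read 8.62 to 8.96 in the control arrays, 8.44 to 8.60 in Myc KO and 8.09 to 8.19 in all 5 QKO arrays. In QKO it changed by -0.64 ± 0.19 (adjusted p = 0.0192, and 0.0631 without control 4). Among the E2f TKO arrays it read 8.22, 8.39 and 8.08 in arrays 1, 3 and 4, but 9.35 and 9.10 in the arrays labelled E2f TKO 2 and 5, above every control array. These same arrays had Cyp1a1 signals of 5.05 and 4.91, against 12.66 to 14.09 in the other 16 arrays. They stay in every comparison as labelled, and some values that rest on the E2f TKO group are also given without them. Over all 5 arrays E2f3 differed from control by -0.15 ± 0.19 in E2f TKO (adjusted p = 0.816). Without the arrays labelled E2f TKO 2 and 5 it was -0.55 (adjusted p = 0.00121), which is no test, since their E2f3 signal helped to single them out. The probe sets of E2f1 and E2f2 showed no fall that passed the test. They changed by -0.24 ± 0.11 for E2f1 and -0.15 ± 0.13 for E2f2 in E2f TKO. A second E2f1 probe set rose, by 0.42 in E2f TKO and 0.74 in QKO (adjusted p = 0.0266 and 4.46e-05, adjusted over every probe set with 1 gene symbol). A probe set outside the deleted part of a gene does not check a deletion. Where these probe sets lie in the deleted alleles was not analysed here.

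**Figure D1:**
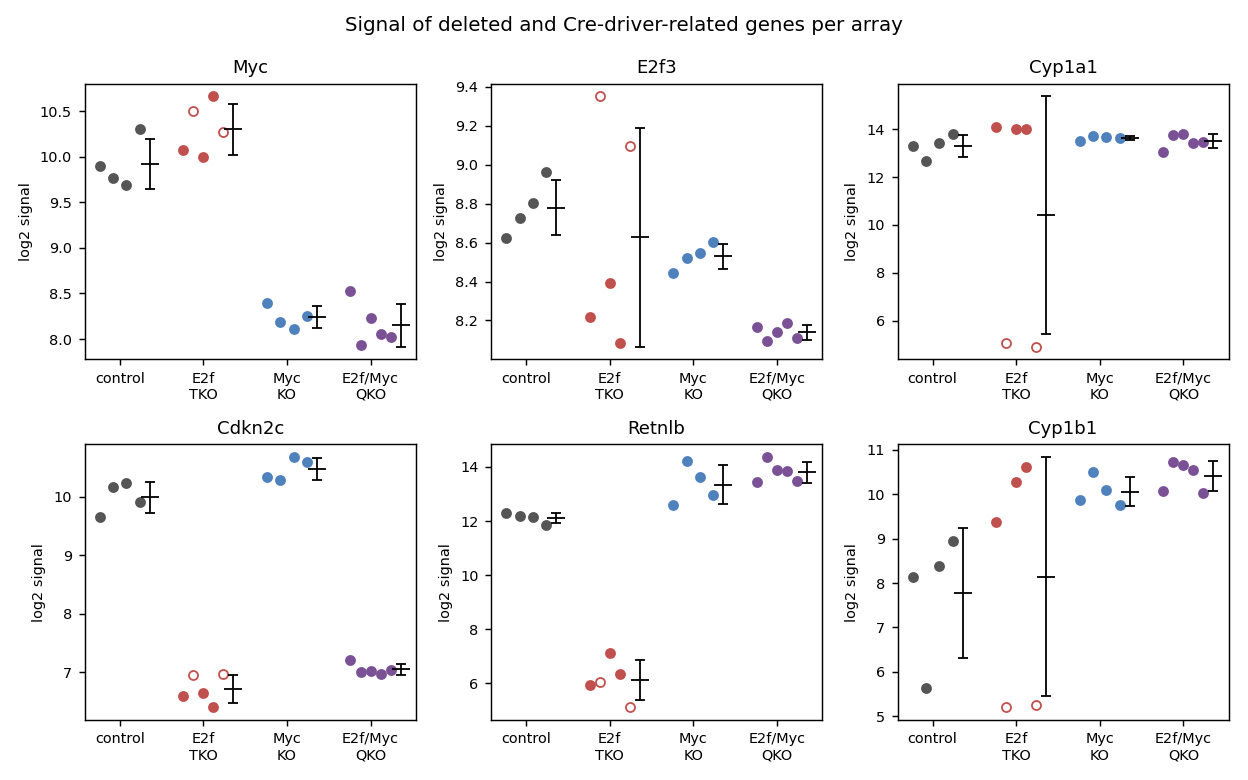
Log2 signal (vertical axis) of Myc, E2f3, Cyp1a1, Cdkn2c, Retnlb and Cyp1b1 in each array, by group (horizontal axis). Bars give the mean and standard deviation of each group, and open circles the arrays labelled E2f TKO 2 and 5. The open circles lie above every control array for E2f3, near 5 for Cyp1a1, and with the other E2f TKO arrays for Cdkn2c and Retnlb.

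Loss of E2f1, E2f2 and E2f3 was compared with control to ask which crypt transcripts depend on these factors. The median of the G1/S (DNA replication) list lay above control and that of the G2/M (mitotic) list below, with most members short of the test, and neither call held with an estimated correlation (adjusted p = 0.926). Of 67 measured G1/S genes, 12 rose and 1 fell (23 and 2 adjusted over the list alone). A median of 0.22 passed (camera adjusted p = 4.33e-11, and adjusted p = 0.926 with an estimated correlation). Cdc6 (0.93 ± 0.18), Cdt1 (0.86 ± 0.13) and Timeless (0.86 ± 0.16), which act in licensing and progress of replication, rose with adjusted p from 0.000947 to 0.00621. Of 81 measured G2/M genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone). A median of -0.38 passed (camera adjusted p = 2.24e-13, and adjusted p = 0.926 with an estimated correlation). The pair that fell were Ndc80 (-0.65 ± 0.16), a kinetochore gene, and Racgap1 (-1.01 ± 0.26), a cytokinesis gene, with adjusted p = 0.0394 and 0.0435. The Ndc80 call was lost when 1 array was left out (control 1, 3 or 4, E2f TKO 3 or 4, Myc KO 1 or 3, QKO 2, 3 or 5, adjusted p 0.0509 to 0.139), in a fit of the 2 groups alone (adjusted p = 0.184) and with Xist as a covariate (adjusted p = 0.0527). The Racgap1 call was lost when 1 array was left out (control 1, 2, 3 or 4, E2f TKO 3 or 4, Myc KO 1, 2, 3 or 4, QKO 3 or 5, adjusted p 0.0529 to 0.13), with the mean of a gene's probe sets (adjusted p = 0.0848), in a fit of the 2 groups alone (adjusted p = 0.192), with a trended, robust eBayes (adjusted p = 0.0519) and with Xist as a covariate (adjusted p = 0.0586). The mitotic list moved most in E2f TKO 1, whose list mean lay -1.15 from the control mean. That array also had the highest enterocyte list mean, at 1.00 above control, a T cell list mean 1.48 above it, and the only G1/S list mean of the group below control, at -0.19. Without E2f TKO 1 the mitotic median was -0.18, and without the arrays labelled E2f TKO 2 and 5 it was -0.58, with 28 members lower (adjusted p = 2.26e-23, and adjusted p = 0.655 with an estimated correlation).

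The enteroendocrine list passed with a higher median after loss of E2f1 to E2f3, though not with an estimated correlation (adjusted p = 0.144), and other list calls were less stable. Of 24 measured enteroendocrine genes, 5 rose and 0 fell (14 and 1 adjusted over the list alone). A median of 0.37 passed (camera adjusted p = 1.41e-10, and adjusted p = 0.144 with an estimated correlation). The hormone gene Gip (0.95 ± 0.13, adjusted p = 0.000255) and the transcription factor gene Neurod1 (0.61 ± 0.09, adjusted p = 0.0012) rose in these crypts. Of 25 measured recombination and Fanconi genes, 2 rose and 0 fell (5 and 2 adjusted over the list alone). A median of 0.19 passed (camera adjusted p = 0.00646, and adjusted p = 0.926 with an estimated correlation). Fancc (0.57 ± 0.09) was the clearest member, though at 0.18 as the mean of its probe sets (adjusted p = 0.0937). No member passed in the lists for nucleotide and one-carbon synthesis, p53 targets and tuft cells, whose medians were 0.13, 0.12 and 0.14 (camera adjusted p = 0.00868 for each, and adjusted p = 0.926 for each with an estimated correlation). The recombination call was lost without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.326), at a median of 0.08. The nucleotide call was lost without control 3, E2f TKO 4 or the array labelled E2f TKO 5 (adjusted p = 0.0612, 0.128 and 0.0673) and without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.307). Its median was 0.06 without E2f TKO 4, 0.08 without both arrays labelled E2f TKO 2 and 5, and 0.27 with 4 members higher without E2f TKO 1. The p53 call was lost without E2f TKO 1 (adjusted p = 0.328), with only genes above the median level (adjusted p = 0.0552) and with array weights (adjusted p = 0.181), and the tuft call without E2f TKO 1 (adjusted p = 0.0644) and with array weights (adjusted p = 0.0887). The p53 median was 0.05 without E2f TKO 1 and 0.22 without both arrays labelled E2f TKO 2 and 5. Genes of the aryl hydrocarbon receptor response, which the inducer of the Cre driver acts on, had a median of -0.31 with none of 8 past the test (camera adjusted p = 0.502). The arrays labelled E2f TKO 2 and 5 were singled out on genes of this list, so a fit without them does not test it. Other lists that did not pass with all arrays passed in that fit. These were the enterocyte list (median 0.38, adjusted p = 0.000238, and adjusted p = 0.809 with an estimated correlation), the T cell list (median 0.81, adjusted p = 3.88e-05, and adjusted p = 0.691 with an estimated correlation), the fibroblast list (median 0.38, adjusted p = 0.00731, and adjusted p = 0.691 with an estimated correlation) and that of enteric neurons and glia (median 0.09, adjusted p = 0.0348, and adjusted p = 0.622 with an estimated correlation). The list of cytosolic ribosomal proteins had a median of -0.07 with all arrays (camera adjusted p = 0.0536), and -0.16 without both (adjusted p = 0.000116, and adjusted p = 0.691 with an estimated correlation).

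The genes raised most in all E2f TKO arrays were St3gal4 (4.85 ± 0.72), a sialyltransferase gene, Amph (3.87 ± 0.31), which encodes the endocytic protein amphiphysin, Defa31 (3.36 ± 0.70), an alpha-defensin gene of Paneth cells, and Cap1 (2.80 ± 0.50), an actin regulator gene. Next were Spata5l1 (2.41 ± 0.29), Epdr1 (2.12 ± 0.22), Tnfrsf14 (2.07 ± 0.37) and Tmem184c (1.98 ± 0.26). Retnlb, a goblet cell gene, had the largest log2 fall (-6.02 ± 0.34, adjusted p = 1.17e-08), to a mean signal of 6.11, near the array median. It was followed by Rbp7 (-4.63 ± 0.43), AI506816 (-4.09 ± 0.72) and Cdkn2c (-3.27 ± 0.13), a CDK4 and CDK6 inhibitor gene. Next came Tmem87a (-2.80 ± 0.49), Nkx6-3 (-2.72 ± 0.47), a homeobox gene, Rims4 (-2.40 ± 0.16) and Ctse (-2.22 ± 0.29). Rbp7, Amph, Cap1, Rims4, Epdr1 and Tnfrsf14 lie within 20 Mb of E2f1, E2f2 or E2f3, where linked variants are a candidate cause. Ctse read 0.09 when probe sets with IDs ending in _s_at or _x_at were left out. The Defa31 call was lost in a fit of the 2 groups alone (adjusted p = 0.0743). E2f7, itself an E2f target, fell as well (-1.23 ± 0.25, adjusted p = 0.0103), though this was lost in a fit of the 2 groups alone (adjusted p = 0.105). Cdkn2d fell beside Cdkn2c (-0.83 ± 0.14, adjusted p = 0.00168), while Ccnd2, the cyclin D2 gene, rose (1.05 ± 0.17, adjusted p = 0.00136). Of 18193 genes tested with limma, 527 passed an adjusted p below 0.05, 305 higher and 222 lower, and 54 genes rose and 54 fell at least 2-fold. Without the arrays labelled E2f TKO 2 and 5, whose E2f3 signal went against their label, 1322 genes passed, 609 higher and 713 lower, and 461 of the 527 were among them. The count was 319 without control 2, 277 without control 3, 323 without control 4, 830 without E2f TKO 1, 330 without E2f TKO 3 and 345 without E2f TKO 4. It was 253 in a fit of the 2 groups alone and 1356 with array weights.

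Loss of Myc was compared with control to ask which crypt transcripts depend on Myc. List medians were lower for ribosomes and nucleotide synthesis and higher for enteroendocrine cells, and none of these calls held with an estimated correlation (adjusted p = 0.294). The 3' minus 5' difference of the actin probe sets, a sign of RNA quality, was 0.31 to 0.44 in the control and 0.18 to 0.22 in the Myc KO arrays, without overlap, and no fit separated it from the genotype. Of 52 measured ribosome biogenesis genes, 0 rose and 33 fell (0 and 46 adjusted over the list alone). A median of -0.60 passed (camera adjusted p = 8.06e-30, and 0.294 with an estimated correlation). Npm1 (-1.07 ± 0.16), which encodes the nucleolar protein nucleophosmin, fell, as did Rcl1 (-0.92 ± 0.14), Nop16 (-0.88 ± 0.14) and Ftsj3 (-0.80 ± 0.13), with adjusted p from 0.00105 to 0.0017. Of 22 measured genes of cytosolic ribosomal proteins, 0 rose and 17 fell (0 and 20 adjusted over the list alone). A median of -0.37 passed (camera adjusted p = 1.47e-17, and 0.294 with an estimated correlation). Of 25 measured nucleotide and one-carbon synthesis genes, 0 rose and 13 fell (0 and 20 adjusted over the list alone). A median of -0.50 passed (camera adjusted p = 2.17e-13, and 0.294 with an estimated correlation). Shmt2 (-1.21 ± 0.21), the mitochondrial serine hydroxymethyltransferase gene, and Cad (-0.95 ± 0.19), which encodes the first enzymes of pyrimidine synthesis, fell. Of 28 measured other known Myc targets, 1 rose and 9 fell (1 and 18 adjusted over the list alone). A median of -0.35 passed (camera adjusted p = 5.48e-08, and 0.563 with an estimated correlation). The member that rose was Ccnd2 (1.51 ± 0.18), while Srm (-0.91 ± 0.19), the spermidine synthase gene, fell.

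Cell cycle genes as a group did not pass in Myc KO crypts. In the G1/S list 0 of 67 measured genes passed, with a median of -0.09 (camera adjusted p = 0.0524). In the G2/M list 1 of 81 rose, with a median of -0.09 (adjusted p = 0.202). Of 24 measured enteroendocrine genes, 3 rose and 0 fell (9 and 0 adjusted over the list alone). A median of 0.33 passed (camera adjusted p = 2.88e-05, and 0.294 with an estimated correlation). Neurod1 (0.57 ± 0.10, adjusted p = 0.00283) rose, and this call was lost with the mean of a gene's probe sets (adjusted p = 0.0672). Of 15 measured Wnt targets, 3 rose and 1 fell (6 and 1 adjusted over the list alone). A median of 0.29 passed (camera adjusted p = 0.0496, and 0.563 with an estimated correlation). Etv4 (1.01 ± 0.15) and Ephb3 (0.77 ± 0.19) rose, and Ccnd1 fell (-0.75 ± 0.20). The Ccnd1 call was lost when 1 array was left out (control 2, 3 or 4, Myc KO 1 or 2, adjusted p 0.0535 to 0.0929). The Wnt list call was lost when 1 array was left out (control 1 or 3, the array labelled E2f TKO 2, E2f TKO 4, Myc KO 1 or 4, QKO 2, adjusted p 0.051 to 0.0814), with the mean of a gene's probe sets (adjusted p = 0.201) and without _s_at and _x_at probe sets (adjusted p = 0.195). Its medians with those probe set choices were 0.17 and 0.11. The tuft cell list had a median of 0.18 (camera adjusted p = 0.0514). It passed without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.0388, and 0.683 with an estimated correlation). The interferon response list passed with a median of 0.38 and no member past the test (camera adjusted p = 0.00566, and adjusted p = 0.883 with an estimated correlation). Its call was lost without control 4 or Myc KO 4 (adjusted p = 0.0544 and 0.418). Its median was 0.16 without Myc KO 4.

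The genes raised most in all Myc KO arrays were Pla2g5 (2.22 ± 0.40), a secreted phospholipase gene, Mcpt2 (1.68 ± 0.39), a mast cell protease gene, Pcp4l1 (1.53 ± 0.32), and Glipr1 (1.52 ± 0.31). Next were Ccnd2 (1.51 ± 0.18), Ctsl (1.42 ± 0.20), Tgfbr2 (1.40 ± 0.25) and Hs3st1 (1.39 ± 0.23). Those lowered most were Car4 (-2.46 ± 0.41), 2010204K13Rik (-1.78 ± 0.24), Snhg4 (-1.75 ± 0.34) and Myc itself. Next came Elobl (-1.58 ± 0.18), Snhg14 (-1.57 ± 0.17), Ccnb1ip1 (-1.53 ± 0.31) and 9130016M20Rik (-1.47 ± 0.20). Their adjusted p ran from 3.12e-05 for Myc to 0.0148 for Mcpt2, whose call was lost without Myc KO 1 or Myc KO 2 (adjusted p = 0.0522 and 0.057). Of 18193 genes tested with limma, 1511 passed an adjusted p below 0.05, 653 higher and 858 lower, and 28 genes rose and 40 fell at least 2-fold. The count was 822 without control 2, 982 without control 3, 664 without control 4, 855 without Myc KO 1 and 640 without Myc KO 2. It was 2681 in a fit of the 2 groups alone, 3427 with array weights and 3014 when every probe set was tested. In the last, 1569 genes had a higher probe set and 1548 a lower one. No Myc KO array had the high Xist signal that control 3, E2f TKO 1 and 4 and QKO 4 and 5 had.

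Loss of all 4 genes was compared with control to ask what their joint loss does to crypt transcripts. List medians were higher for replication and for enteroendocrine, tuft and stem cells and lower for mitosis, ribosomes and nucleotide synthesis, and none of these calls held with an estimated correlation (adjusted p = 0.234 to 0.641). The actin difference was 0.19 to 0.31 in the QKO arrays, and only QKO 2 reached the control range. Of 67 measured G1/S genes, 38 rose and 4 fell (40 and 5 adjusted over the list alone). A median of 0.47 passed (camera adjusted p = 4.7e-08, and 0.641 with an estimated correlation). Timeless (1.63 ± 0.16), Orc1 (0.95 ± 0.10) and Rfc2 (0.98 ± 0.11) rose, with adjusted p from 4.63e-06 to 1.56e-05. Ccne2, the cyclin E2 gene, was the member that fell most clearly (-1.85 ± 0.20, adjusted p = 1.03e-05). Of 81 measured G2/M genes, 0 rose and 47 fell (0 and 55 adjusted over the list alone). A median of -0.61 passed (camera adjusted p = 3.02e-17, and 0.497 with an estimated correlation). Nusap1 (-2.11 ± 0.27), a spindle protein gene, and Espl1 (-1.83 ± 0.24), the separase gene, fell. Of 25 measured recombination and Fanconi genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone). A median of 0.34 passed (camera adjusted p = 0.006, and 0.698 with an estimated correlation). Among those that rose were Rad54l (1.44 ± 0.17) and Rad51c (0.81 ± 0.09).

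**Figure D2:**
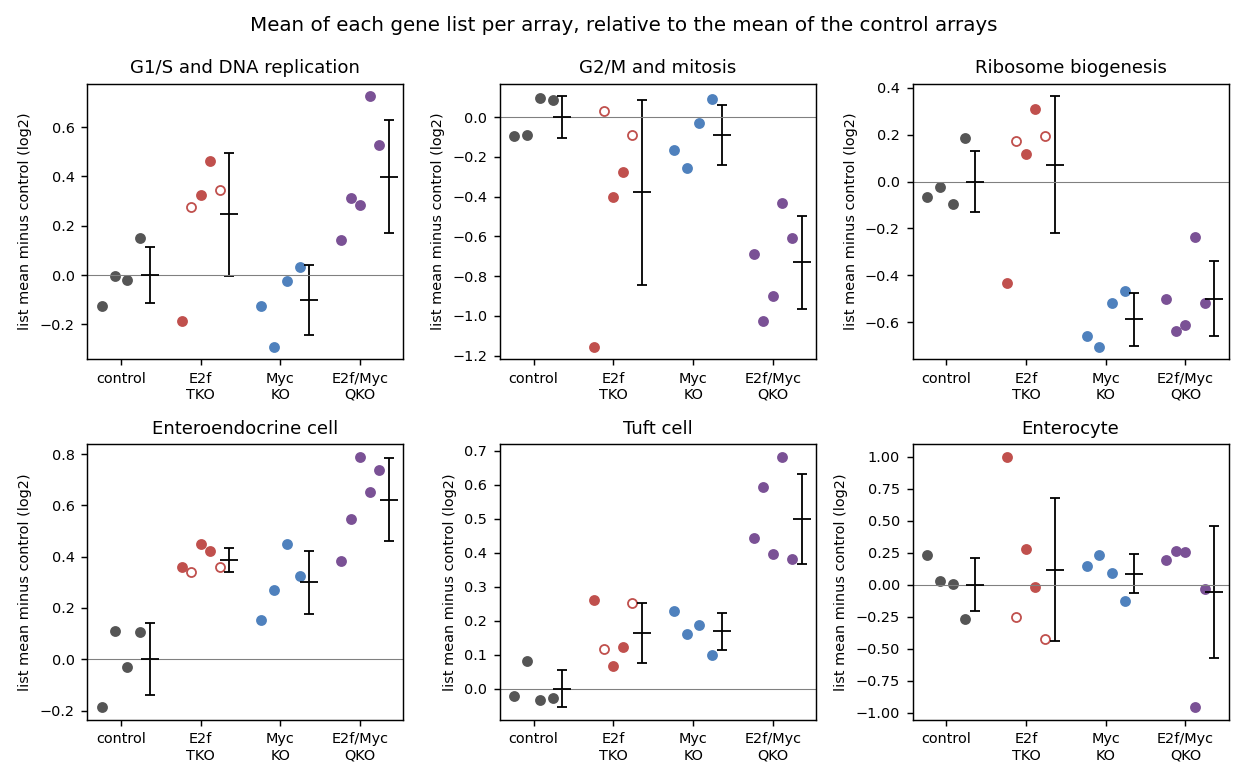
Mean log2 signal of 6 gene lists in each array, relative to the mean of the control arrays (vertical axis), by group (horizontal axis). Bars give the mean and standard deviation of each group, and open circles the arrays labelled E2f TKO 2 and 5. The 5 QKO arrays lie above 0 for G1/S, enteroendocrine and tuft cell genes and below 0 for G2/M and ribosome biogenesis genes, and the enterocyte list spreads widely within E2f TKO and QKO.

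The lists of ribosomes, nucleotide synthesis and other Myc targets passed with lower medians in QKO crypts, at the preset correlation only. Of 52 measured ribosome biogenesis genes, 0 rose and 35 fell (0 and 39 adjusted over the list alone). A median of -0.43 passed (camera adjusted p = 2.1e-16, and adjusted p = 0.497 with an estimated correlation). Nop16 (-0.82 ± 0.13) and Rcl1 (-0.80 ± 0.13) fell. Of 22 measured genes of cytosolic ribosomal proteins, 0 rose and 15 fell (0 and 19 adjusted over the list alone). A median of -0.30 passed (camera adjusted p = 2.86e-09, and adjusted p = 0.497 with an estimated correlation). Rpl37 (-1.10 ± 0.14) fell. Of 25 measured nucleotide and one-carbon synthesis genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone). A median of -0.27 passed (camera adjusted p = 6.43e-05, and adjusted p = 0.591 with an estimated correlation). Cad (-1.25 ± 0.18) and Dhodh (-1.10 ± 0.16), both of pyrimidine synthesis, fell. Of 28 measured other known Myc targets, 2 rose and 16 fell (3 and 16 adjusted over the list alone). A median of -0.33 passed (camera adjusted p = 5.11e-05, and adjusted p = 0.591 with an estimated correlation). Ccnd2 (2.07 ± 0.17) and Hk2 (1.48 ± 0.22), the hexokinase 2 gene, rose. After quantile normalization the nucleotide median was -0.16 and the Myc target median -0.20.

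The enteroendocrine, tuft and stem cell lists passed with higher medians in QKO crypts, at the preset correlation only. Of 24 measured enteroendocrine genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone). A median of 0.63 passed (camera adjusted p = 4.7e-08, and adjusted p = 0.234 with an estimated correlation). Among those that rose were the hormone genes Gip (1.41 ± 0.13) and Sst (1.23 ± 0.15) and Reg4 (1.18 ± 0.13). Of 14 measured tuft cell genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone). A median of 0.53 passed (camera adjusted p = 5.91e-06, and adjusted p = 0.234 with an estimated correlation). Among those that rose were Avil (0.89 ± 0.12) and Trpm5 (0.66 ± 0.10). Of 17 measured crypt stem cell genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). A median of 0.52 passed (camera adjusted p = 0.00827, and adjusted p = 0.608 with an estimated correlation). Prom1 (1.23 ± 0.21) and Tnfrsf19 (1.75 ± 0.31) rose. Of 15 measured Wnt targets, 8 rose and 0 fell (8 and 0 adjusted over the list alone). A median of 0.36 passed (camera adjusted p = 0.000966, and adjusted p = 0.275 with an estimated correlation). Etv4 (1.61 ± 0.14) and Ephb3 (1.24 ± 0.18) rose. The Wnt median was 0.23 with the mean of a gene's probe sets. Markers of endothelium, a cell type outside the epithelium, also passed. Of 13 measured endothelial genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone). A median of 0.20 passed (camera adjusted p = 0.035, and adjusted p = 0.497 with an estimated correlation). Lyve1 (0.63 ± 0.09) was among those that rose. The endothelial call was lost without control 2, control 3, QKO 2 or QKO 3 (adjusted p = 0.0728, 0.0672, 0.0656 and 0.0887), after quantile normalization (adjusted p = 0.194), with only genes above the median level (adjusted p = 0.0661) and without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.05). Its median was 0.12 without control 2, 0.11 after quantile normalization and 0.36 with only genes above the median level. The array QKO 4 stood apart in its enterocyte list mean, -0.96 from control.

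The genes raised most in all QKO arrays were St3gal4 (4.98 ± 0.72), Amph (3.06 ± 0.31), Adgrg6 (2.87 ± 0.17), an adhesion receptor gene, Pla2g5 (2.80 ± 0.38), and Trim30d (2.79 ± 0.98). Next were Sptssb (2.69 ± 0.64), Tgfbr2 (2.54 ± 0.23) and Glipr1 (2.37 ± 0.30). Those lowered most were Rbp7 (-4.95 ± 0.43), to a mean signal of 6.19 near the array median, Car4 (-4.00 ± 0.39), Cdkn2c (-2.94 ± 0.13), and Rims4 (-2.72 ± 0.16). Next came Gsdmc2 (-2.62 ± 0.51), H2-Bl (-2.42 ± 0.51), H2bc21 (-2.37 ± 0.34) and Pyroxd2 (-2.37 ± 0.22). Apart from Trim30d, their adjusted p ran from 4.01e-10 for Cdkn2c to 0.00542 for Sptssb. The Trim30d call (adjusted p = 0.0421) was lost when 1 array was left out (control 1 or 2, E2f TKO 3, QKO 1, 2, 3, 4 or 5, adjusted p 0.0511 to 0.168), with a trended, robust eBayes (adjusted p = 0.0644), with array weights (adjusted p = 0.0585), with Xist as a covariate (adjusted p = 0.0634) and without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.0519). E2f7 (-2.01 ± 0.25), Rb1 (-0.89 ± 0.13) and Cdkn2d (-1.04 ± 0.14) fell in QKO crypts. Of 18193 genes tested with limma, 4888 passed an adjusted p below 0.05, 2602 higher and 2286 lower, and 220 genes rose and 163 fell at least 2-fold. With only genes above the median level the balance turned, with 1879 higher and 2220 lower.

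QKO crypts were compared with E2f TKO crypts to ask what loss of Myc adds where E2f1 to E2f3 are lost. List medians were lower for ribosomes and nucleotide synthesis and higher for tuft and enteroendocrine cells and Wnt targets, and none of these calls held with an estimated correlation (adjusted p = 0.28 to 0.537). Of 52 measured ribosome biogenesis genes, 0 rose and 40 fell (0 and 48 adjusted over the list alone). A median of -0.57 passed (camera adjusted p = 3.77e-28, and adjusted p = 0.28 with an estimated correlation). Nop16 (-1.07 ± 0.13) and Polr1b (-1.09 ± 0.16), a subunit gene of RNA polymerase I, fell. Of 25 measured nucleotide and one-carbon synthesis genes, 0 rose and 15 fell (0 and 16 adjusted over the list alone). A median of -0.43 passed (camera adjusted p = 1.87e-11, and adjusted p = 0.28 with an estimated correlation). Of 22 measured genes of cytosolic ribosomal proteins, 0 rose and 9 fell (0 and 16 adjusted over the list alone). A median of -0.24 passed (camera adjusted p = 2.63e-09, and adjusted p = 0.396 with an estimated correlation). The ribosomal protein median was -0.14, with 2 genes lower, without the arrays labelled E2f TKO 2 and 5, and -0.14 after quantile normalization. Of 28 measured other known Myc targets, 2 rose and 15 fell (3 and 20 adjusted over the list alone). A median of -0.37 passed (camera adjusted p = 2.01e-08, and adjusted p = 0.396 with an estimated correlation). Srm (-1.30 ± 0.17) was lower and Ccnd2 (1.02 ± 0.16) higher. Of 14 measured tuft cell genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). A median of 0.35 passed (camera adjusted p = 0.000117, and adjusted p = 0.28 with an estimated correlation). Avil rose (0.74 ± 0.11). Of 24 measured enteroendocrine genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone). A median of 0.22 passed (camera adjusted p = 0.0119, and adjusted p = 0.537 with an estimated correlation). The enteroendocrine median was 0.15 without QKO 3. Of 15 measured Wnt targets, 7 rose and 0 fell (8 and 0 adjusted over the list alone). A median of 0.27 passed (camera adjusted p = 0.00132, and adjusted p = 0.28 with an estimated correlation). Etv4 rose (1.47 ± 0.13). The Wnt median was 0.42 without the arrays labelled E2f TKO 2 and 5.

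Cell cycle, stem cell and endothelial lists also passed between QKO and E2f TKO crypts, at the preset correlation only. Of 81 measured G2/M genes, 0 rose and 13 fell (0 and 19 adjusted over the list alone). A median of -0.28 passed (camera adjusted p = 2.01e-08, and adjusted p = 0.819 with an estimated correlation). Espl1 fell (-1.17 ± 0.23). The mitotic median was -0.48 without E2f TKO 1, -0.16 without the array labelled E2f TKO 2, and -0.05 without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.0439, and adjusted p = 0.928 with an estimated correlation). Of 67 measured G1/S genes, 14 rose and 5 fell (16 and 5 adjusted over the list alone). A median of 0.19 passed (camera adjusted p = 0.0138, and adjusted p = 0.948 with an estimated correlation). Orc1 rose (0.65 ± 0.09) while Ccne2 fell (-1.04 ± 0.19). The G1/S call was lost without E2f TKO 1, QKO 4 or QKO 5 (adjusted p = 0.803, 0.415 and 0.118) and with array weights (adjusted p = 0.721). Its medians there were 0.10, 0.12, 0.15 and 0.09. Of 17 measured crypt stem cell genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone). A median of 0.37 passed (camera adjusted p = 0.0252, and adjusted p = 0.819 with an estimated correlation). Hopx rose (0.57 ± 0.06). The stem cell call was lost without E2f TKO 1, E2f TKO 3 or QKO 4 (adjusted p = 0.283, 0.0528 and 0.146), without _s_at and _x_at probe sets (adjusted p = 0.0735) and in a fit of the 2 groups alone (adjusted p = 0.0523). Its median was 0.20 without E2f TKO 1, 0.18 without those probe sets and 0.60 without both arrays labelled E2f TKO 2 and 5. Of 13 measured endothelial genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). A median of 0.20 passed (camera adjusted p = 0.0138, and adjusted p = 0.396 with an estimated correlation). Lyve1 rose (0.46 ± 0.09), which was lost with the mean of a gene's probe sets (adjusted p = 0.0775). The endothelial call was lost after quantile normalization (adjusted p = 0.0999) and with only genes above the median level (adjusted p = 0.115), with a median of 0.11 in the first. Without both arrays labelled E2f TKO 2 and 5, lists passed that did not pass with all arrays, namely T cells (median -0.74, adjusted p = 0.00202, and adjusted p = 0.615 with an estimated correlation), enterocytes (median -0.34, adjusted p = 7.06e-05, and adjusted p = 0.639 with an estimated correlation), goblet cells (median 0.23, adjusted p = 0.0119, and adjusted p = 0.538 with an estimated correlation) and homologous recombination (median 0.24, adjusted p = 0.0163, and adjusted p = 0.823 with an estimated correlation). The aryl hydrocarbon receptor list passed there too (median -0.40, adjusted p = 0.00561, and adjusted p = 0.493 with an estimated correlation), but these arrays were singled out on it, so this is no test.

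The genes furthest above E2f TKO in QKO crypts were Retnlb (7.69 ± 0.32, adjusted p = 1.39e-10), whose E2f TKO signal lay near the array median, Acta1 (2.53 ± 0.85), the skeletal muscle actin gene, Pla2g5 (2.21 ± 0.36), Gkn3 (2.00 ± 0.53), a gastrokine gene, and Nkx6-3 (1.83 ± 0.44). Those furthest below were Car4 (-3.18 ± 0.37), Defa31 (-3.03 ± 0.66), Cap1 (-2.98 ± 0.47), Ccnb1ip1 (-2.46 ± 0.28) and Mt2 (-2.22 ± 0.50). The Acta1 value was 0.59 without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.259). Its call was lost in every fit that left out 1 array (adjusted p 0.0527 to 0.126) except those without E2f TKO 1, 3 or 4. It was also lost with the mean of a gene's probe sets (adjusted p = 0.051), in a fit of the 2 groups alone (adjusted p = 0.142), with a trended, robust eBayes (adjusted p = 0.0734), with array weights (adjusted p = 0.112) and with Xist as a covariate (adjusted p = 0.0534). The Gkn3 and Nkx6-3 calls were lost in a fit of the 2 groups alone (adjusted p = 0.0563 and 0.0533). Of 18193 genes tested with limma, 3100 passed an adjusted p below 0.05, 1653 higher and 1447 lower, and 61 genes rose and 62 fell at least 2-fold. Without both arrays labelled E2f TKO 2 and 5, 2155 genes passed, 1193 higher and 962 lower, and 1657 of the 3100 were among them. The balance turned with only genes above the median level, with 1243 higher and 1479 lower, and without E2f TKO 1, with 2072 higher and 2216 lower. The count was 1549 in a fit of the 2 groups alone and 4742 when every probe set was tested.

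QKO crypts were compared with Myc KO crypts to ask what loss of E2f1 to E2f3 adds where Myc is lost. List medians were higher for replication, DNA repair and enteroendocrine and tuft cells and lower for mitosis, and none of these calls held with an estimated correlation (adjusted p = 0.45 to 0.474). Of 67 measured G1/S genes, 36 rose and 1 fell (47 and 4 adjusted over the list alone). A median of 0.51 passed (camera adjusted p = 3.35e-21, and adjusted p = 0.474 with an estimated correlation). Cdt1 (1.23 ± 0.13), Timeless (1.53 ± 0.16) and Gins2 (1.33 ± 0.17) rose. Of 81 measured G2/M genes, 0 rose and 31 fell (1 and 50 adjusted over the list alone). A median of -0.53 passed (camera adjusted p = 1.06e-24, and adjusted p = 0.474 with an estimated correlation). Nusap1 (-2.02 ± 0.27) and Espl1 (-1.46 ± 0.24) fell. Of 25 measured recombination and Fanconi genes, 11 rose and 1 fell (17 and 1 adjusted over the list alone). A median of 0.39 passed (camera adjusted p = 3.8e-08, and adjusted p = 0.474 with an estimated correlation). Rad54l (1.36 ± 0.17) and Brca1 (0.94 ± 0.15) rose. Of 24 measured enteroendocrine genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone). A median of 0.33 passed (camera adjusted p = 9.39e-05, and adjusted p = 0.474 with an estimated correlation). Of 14 measured tuft cell genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone). A median of 0.31 passed (camera adjusted p = 7.39e-06, and adjusted p = 0.45 with an estimated correlation). Ribosome biogenesis genes did not pass, with a median of 0.09 and none of 52 past the test (camera adjusted p = 0.197).

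Other list calls between QKO and Myc KO crypts were less stable. Of 23 measured interferon response genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone). A median of -0.39 passed (camera adjusted p = 9.39e-05, and adjusted p = 0.76 with an estimated correlation). Psmb9 (-0.79 ± 0.12) and Tap1 (-1.09 ± 0.25), both of antigen processing, fell. The interferon call was lost without Myc KO 4 (adjusted p = 0.178). Its median was then -0.17, while without Myc KO 3 the median was -0.64. Of 29 measured p53 targets, 4 rose and 0 fell (8 and 0 adjusted over the list alone). A median of 0.15 passed (camera adjusted p = 0.0184, and adjusted p = 0.76 with an estimated correlation). The p53 list call was lost without QKO 3 (adjusted p = 0.0576) and with the mean of a gene's probe sets (adjusted p = 0.057). Of 15 measured Wnt targets, 2 rose and 0 fell (2 and 0 adjusted over the list alone). A median of 0.23 passed (camera adjusted p = 0.0137, and adjusted p = 0.474 with an estimated correlation). The Wnt list call was lost without QKO 4 (adjusted p = 0.0633) and with only genes above the median level (adjusted p = 0.0661). Its median was 0.39 in the last of these and 0.15 with the mean of a gene's probe sets. Of 25 measured nucleotide and one-carbon synthesis genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone). A median of 0.16 passed (camera adjusted p = 0.0202, and adjusted p = 0.849 with an estimated correlation). The nucleotide list call was lost without Myc KO 2 or QKO 4 (adjusted p = 0.113 and 0.141). The crypt stem cell list passed with a median of 0.15 and none of 17 past the test (camera adjusted p = 0.0239, and adjusted p = 0.796 with an estimated correlation), and the call was lost without Myc KO 2 or QKO 4 (adjusted p = 0.0814 and 0.163) and with the replicate number as a block (adjusted p = 0.0563).

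The genes furthest above Myc KO in QKO crypts were St3gal4 (5.20 ± 0.72), Trim30d (4.16 ± 0.98), Amph (2.72 ± 0.31), Muc4 (2.60 ± 0.45), a membrane mucin gene, and Trim12a (2.18 ± 0.64). Those furthest below were Rbp7 (-3.85 ± 0.43), Cdkn2c (-3.42 ± 0.13), the mast cell protease genes Mcpt2 (-3.37 ± 0.37) and Mcpt1 (-3.31 ± 0.38), and Bcl2l15 (-2.23 ± 0.66). The Trim30d call was lost without Myc KO 2 or Myc KO 3 (adjusted p = 0.0544 and 0.0533). The Trim12a call (adjusted p = 0.0435) was lost when 1 array was left out (E2f TKO 3 or 4, the array labelled E2f TKO 5, Myc KO 1, 2 or 3, QKO 1, 2, 3, 4 or 5, adjusted p 0.0502 to 0.142), with the replicate number as a block (adjusted p = 0.0577), with a trended, robust eBayes (adjusted p = 0.0705), with Xist as a covariate (adjusted p = 0.125) and without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.0502). The Bcl2l15 call (adjusted p = 0.0464) was lost when 1 array was left out (control 1, 2, 3 or 4, the array labelled E2f TKO 2, E2f TKO 3 or 4, Myc KO 1, 2 or 3, QKO 1, 2, 4 or 5, adjusted p 0.0509 to 0.17), with the replicate number as a block (adjusted p = 0.0694), with a trended, robust eBayes (adjusted p = 0.0753) and with Xist as a covariate (adjusted p = 0.0947). Of 18193 genes tested with limma, 1398 passed an adjusted p below 0.05, 836 higher and 562 lower, and 101 genes rose and 71 fell at least 2-fold. The count was 918 without Myc KO 3, 921 without Myc KO 4 and 2265 with array weights.

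The interaction asked whether the joint loss departed from the sum of the single changes on the log2 scale. Retnlb departed most, at 6.47 ± 0.48, adjusted p = 2.05e-06. It fell by 6.02 in E2f TKO crypts, rose by 1.22 in Myc KO (adjusted p = 0.0422) and by 1.68 in QKO (adjusted p = 0.00161). Its call in Myc KO was lost when 1 array was left out (control 1, 2, 3 or 4, Myc KO 2 or 3, QKO 3, adjusted p 0.0528 to 0.152), with a trended, robust eBayes (adjusted p = 0.058) and with Xist as a covariate (adjusted p = 0.0591). The joint change also lay above the sum for Scpep1 (1.61 ± 0.23, adjusted p = 0.00798) and 9930104L06Rik (1.497 ± 0.18, adjusted p = 0.00136). The test also passed for Elobl (1.90 ± 0.25, adjusted p = 0.00326) and Rims2 (1.34 ± 0.23, adjusted p = 0.0373). Elobl means of 5.16, 5.55 and 5.48 in E2f TKO, Myc KO and QKO crypts lay below the array medians. So did Rims2 means of 5.27, 5.50 and 5.24 in control, E2f TKO and Myc KO crypts. A change there is not shown to be measurable, so neither departure is interpreted. The joint change lay below the sum for Cap1 (-4.34 ± 0.71, adjusted p = 0.0253), Amacr (-1.42 ± 0.21, adjusted p = 0.00861) and Cebpb (-0.53 ± 0.09, adjusted p = 0.0484). Cap1 and 9930104L06Rik lie within 20 Mb of a deleted E2f gene, where linked variants are a candidate. They changed by 2.80 and -1.31 in E2f TKO but by -0.19 and -0.004 in QKO. Of 18193 genes tested with limma, 10 passed, 7 above and 3 below the sum. The fit without both arrays labelled E2f TKO 2 and 5 also gave 10 genes, 6 of them the same genes, and ended the calls of Rims2, Cap1 and Cebpb (adjusted p = 0.0806, 0.0763 and 0.0763). The count was 6 without control 2, 3 or 4 or the array labelled E2f TKO 2, 5 with only genes above the median level, 22 when every probe set was tested and 4 without genes near the deleted genes. The Cap1 call was also lost when 1 array was left out (control 2, 3 or 4, the array labelled E2f TKO 2, Myc KO 1 or 2, QKO 1 or 2, adjusted p 0.0509 to 0.0983) and with a trended, robust eBayes (adjusted p = 0.0644). The Rims2 call was also lost when 1 array was left out (control 1, 2, 3 or 4, an array labelled E2f TKO 2 or 5, E2f TKO 3, Myc KO 1, 3 or 4, QKO 1, 2 or 4, adjusted p 0.0529 to 0.12), with the mean of a gene's probe sets (adjusted p = 0.188), without _s_at and _x_at probe sets (adjusted p = 0.952) and with the replicate number as a block (adjusted p = 0.081), and it read 0.11 without _s_at and _x_at probe sets. The Cebpb call was also lost when 1 array was left out (control 1, 2, 3 or 4, E2f TKO 1 or 4, the array labelled E2f TKO 2, Myc KO 1, 2, 3 or 4, QKO 2, 3 or 4, adjusted p 0.0575 to 0.147), after quantile normalization (adjusted p = 0.0729), with only genes above the median level (adjusted p = 0.0501), with the mean of a gene's probe sets (adjusted p = 0.18), without _s_at and _x_at probe sets (adjusted p = 0.0535), with the replicate number as a block (adjusted p = 0.081), with a trended, robust eBayes (adjusted p = 0.0644) and with Xist as a covariate (adjusted p = 0.06).

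Among the gene lists the interaction passed for 8, though no single member of these lists did. The G1/S list had a median of 0.32 (camera adjusted p = 7.48e-09, and adjusted p = 0.986 with an estimated correlation), and 0.20 without E2f TKO 1 and 0.21 with array weights. The list of cytosolic ribosomal proteins had a median of 0.13 (camera adjusted p = 0.000279, and adjusted p = 0.986 with an estimated correlation), 0.08 without Myc KO 2 and 0.22 without both arrays labelled E2f TKO 2 and 5. The homologous recombination list had a median of 0.21 (camera adjusted p = 0.000279, and adjusted p = 0.986 with an estimated correlation). This recombination call was lost without E2f TKO 1 (adjusted p = 0.0596), at a median of 0.12. The G2/M list had a median of -0.21 (camera adjusted p = 3.27e-07, and adjusted p = 0.986 with an estimated correlation), -0.42 without E2f TKO 1, -0.13 without the array labelled E2f TKO 2, and 0.03 without both arrays labelled E2f TKO 2 and 5 (adjusted p = 0.631, and adjusted p = 0.919 with an estimated correlation). The tuft cell list had a median of 0.16 (camera adjusted p = 0.0233, and adjusted p = 0.986 with an estimated correlation). This tuft call was lost when 1 array was left out (control 2, E2f TKO 3 or 4, Myc KO 4, QKO 2 or 4, adjusted p 0.0564 to 0.13) and with only genes above the median level (adjusted p = 0.0709), and its median was 0.10 without QKO 4. The enterocyte list had a median of -0.23 (camera adjusted p = 0.0127, and adjusted p = 0.986 with an estimated correlation). This enterocyte call was lost without control 4, E2f TKO 1, E2f TKO 3 or QKO 4 (adjusted p = 0.141, 0.768, 0.0591 and 0.574) and with only genes above the median level (adjusted p = 0.0547). The enterocyte median was -0.02 without E2f TKO 1 and -0.03 without QKO 4. It was -0.37 without the array labelled E2f TKO 5, -0.12 with array weights, and -0.57 without both arrays labelled E2f TKO 2 and 5 (adjusted p = 1.03e-07, and adjusted p = 0.769 with an estimated correlation). The interferon list had a median of -0.20 (camera adjusted p = 0.0247, and adjusted p = 0.986 with an estimated correlation). This interferon call was lost when 1 array was left out (control 2 or 4, E2f TKO 1 or 3, QKO 1, 3 or 4, adjusted p 0.051 to 0.397), with only genes above the median level (adjusted p = 0.148) and with array weights (adjusted p = 0.122). Its median was -0.40 without control 1, -0.10 without control 4, -0.09 without E2f TKO 1, -0.47 without Myc KO 3 and -0.34 without both arrays labelled E2f TKO 2 and 5. It changed sign without Myc KO 4, at 0.02 (adjusted p = 0.961). The T cell list had a median of -0.56 (camera adjusted p = 0.0345, and adjusted p = 0.986 with an estimated correlation). This T cell call was lost when 1 array was left out (control 2, 3 or 4, E2f TKO 1, 3 or 4, Myc KO 1 or 2, QKO 1, 3, 4 or 5, adjusted p 0.051 to 0.544) and with only genes above the median level (adjusted p = 0.144). The T cell median was -0.89 without control 1, -0.21 without E2f TKO 1, -0.87 without the array labelled E2f TKO 5, and -1.18 without both arrays labelled E2f TKO 2 and 5 (adjusted p = 3.1e-08, and adjusted p = 0.769 with an estimated correlation). In that last fit the lists of stem cells (median 0.29, adjusted p = 0.00453, and adjusted p = 0.769 with an estimated correlation), Wnt targets (median 0.30, adjusted p = 0.0455, and adjusted p = 0.769 with an estimated correlation) and fibroblasts (median -0.29, adjusted p = 0.0149, and adjusted p = 0.787 with an estimated correlation) also passed. So did the aryl hydrocarbon receptor list (median -1.12, adjusted p = 1.73e-06, and adjusted p = 0.356 with an estimated correlation), which is no test, since these arrays were singled out on it.

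Changes of the same direction were counted between genotypes, in comparisons that use the same control arrays. Of the genes changed in E2f TKO and in Myc KO crypts, 52 rose in both and 28 fell in both. Of the rest 12 went opposite ways. Independent lists of these sizes would share 10.9 higher and 10.5 lower genes. With the 4 control arrays split so that each genotype had its own pair, 10 to 17 genes changed the same way in both, against 80 with shared controls. Across genes, which are not independent replicates, the log2 differences of E2f TKO and Myc KO had a Pearson r of 0.228, against 0.529 in 100 simulations of unchanged groups against the same controls, and of -0.02 to 0.14 with split controls. Their covariance was 0.0144, against 0.0115 in the simulations, and 0.00404 on average with split controls. QKO shared 436 changes of the same direction with E2f TKO (260 higher and 176 lower, where independent lists would share 43.6 and 27.9). It shared 1179 with Myc KO (513 and 666, where independent lists would share 93.4 and 108). The covariances with QKO were 0.0596 for E2f TKO and 0.0591 for Myc KO, against 0.0115 in both simulations. Part of each excess with QKO can come from the shared controls.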

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

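The tests of a wrong label, Cre induction, RNA integrity, linked variants, the count of second probe sets against other genes, the share of dividing cells and the share of enterocytes, and the fits without the arrays labelled E2f TKO 2 and 5, were chosen only after the result was seen.

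The arrays labelled E2f TKO 2 and 5 had less Cyp1a1 (5.05 and 4.91, against 12.66 or more), Cyp1b1, Cyp1a2 and Ahrr than any other array. Over 38 genes that separate E2f TKO 1, 3 and 4 (position 1) from control (position 0) by 4-fold, their median positions were 0.586 and 0.465, between the highest control or Myc KO array (0.343) and the lowest QKO array (0.655), which argues against arrays of another group under a wrong label, but this bound replaced a first one of 0.5 after the value was seen, and by the first one the test would have stayed open. The difference of 3' and 5' actin probe sets in the array labelled E2f TKO 5, 0.30, lay within the range of the other groups, which argues against poor RNA integrity as the shared cause, while that of the array labelled E2f TKO 2 was 0.78 and leaves it open there. E2f3 signals of 9.10 and 9.35, no lower than in any control, would fit mice in which the Cre driver was not induced, but Cdkn2c (6.95 and 6.97, against 9.66 to 10.23 in control) and Retnlb (6.06 and 5.11, against 11.86 to 12.30) lay below every control array, which argues against it if the driver deleted all 3 genes and leaves it open if E2f1 and E2f2 were already missing in the germline, a point that the tables do not settle. A biological difference between mice of 1 group stays open and was not tested.

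In all E2f TKO arrays, 97 genes with a position in the reference changed at least 2-fold without overlap with control. Of these, 15 lay within 20 Mb of E2f1, E2f2 or E2f3, 1.26% of the genes there against 0.484% elsewhere (odds ratio 2.63, one-sided Fisher's exact test, p = 0.00154), with Rbp7, Amph, Cap1, Rims4, Epdr1 and Tnfrsf14 among them, 10 of them near E2f2. Variants carried along with the targeted loci are therefore a candidate explanation for a part of this set, though the odds ratio was 1.43 (same exact test, p = 0.283) within 10 Mb and 2.05 (p = 0.0105) within 30 Mb, and 1.48 (p = 0.24) for the genes changed in Myc KO. Of 31 genes with another probe set of above-median level, 29 had the same sign there and 23 passed in the same direction, against 1.26 expected from the other genes on the array, which argues against a variant under 1 probe set for those 23, while for the rest of the 97 it cannot be told apart from a change of the transcript, as too few have a second probe set and the share of 74.2% lay just under the bound of 75% set before. The 82 genes elsewhere, Retnlb and St3gal4 among them, lie further away, but a test by distance does not clear them of variants elsewhere in the genome. Retnlb changed by -6.02 in E2f TKO but by 1.68 in QKO crypts, which are labelled as lacking the same E2f genes. Loss of E2f1 to E2f3 itself stays open for all 97.

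In QKO crypts the G1/S list median lay above control and the G2/M median below. A lower share of dividing cells alone would lower both lists. The G1/S median of 0.47 is part of the pattern to be explained, so it is no separate test of this. A lower share beside other causes stays open. Whether more enterocytes add to the G2/M fall stays open, since the enterocyte list mean differed by only -0.06 (SD 0.52 among QKO arrays), so that its use as a covariate, with a G2/M median of -0.65, decides nothing. Loss of the 4 deleted genes itself stays open as a cause and was not tested apart from these.

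Other splits of the same arrays seldom gave as many genes. For E2f TKO against control 1 of 100 splits, the real one, gave 527 genes, and the highest other gave 26. For Myc KO it was 1 of 35, with 1511 genes against 2, and for QKO 1 of 100, with 4888 against 2224. For QKO against Myc KO it was 1 of 100, with 1398 against 217. Chance can be excluded at the 5% level for these. For QKO against E2f TKO 2 of 100 splits gave as many, the real one with 3100 and another with 3353. That share is under 5%, but a count that another split exceeds does not single out the genotype. The split with 3353 genes sets E2f TKO 1 with QKO 1, 2, 3 and 5 against QKO 4 and the other E2f TKO arrays. E2f TKO 1 and QKO 4 have the highest and the lowest enterocyte list mean of all arrays, which points to a structure of the samples beside the genotype.

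A test for an array far from the rest of its group was run on 352 groups of values, where chance gives about 1 in 20, or 17.6, and 32 stood apart. Among array measures these were the actin difference of the array labelled E2f TKO 2 given above, and the mean poly-A spike signal of control 1 (8.54) and of E2f TKO 4 (7.65). E2f TKO 1 stood apart in list means relative to control for G1/S (-0.19), ribosome biogenesis (-0.43), nucleotide synthesis (-0.33), other Myc targets (-0.36), CDK inhibitors and G1 cyclins (-0.34), p53 targets (0.59), Paneth cells (-0.43) and interferon response (0.32). The same array stood apart in the log2 signals of Cap1 (11.41), Muc4 (7.91) and Trim12a (7.53). Other list means that stood apart were other Myc targets in control 4 (0.12), tuft cells in control 2 (0.0818), endothelium in control 1 (0.14), the E2f, Rb and Myc family in Myc KO 2 (-0.20), myeloid cells in E2f TKO 4 (0.73) and enterocytes in QKO 4 (-0.96). In Myc KO arrays the signals of Amph (4.30), Tmem184c (6.18) and Rbp7 (8.88) in array 2 and of Trim12a (6.48) in array 4 stood apart. In QKO arrays those of Tmem184c (5.53) and Acta1 (11.84) in array 1, Rims4 (5.61) in array 4, and Ccnb1ip1 (4.79) and Mt2 (12.85) in array 5 did. The remaining ones were St3gal4 (7.65) in the array labelled E2f TKO 2, Nkx6-3 (6.83) in the array labelled E2f TKO 5 and Gsdmc2 (5.42) in control 4.

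The interaction, whether the effect of E2f loss differs with and without Myc, passed for 10 genes. Departures were Retnlb 6.47, Cap1 -4.34, Scpep1 1.61, 9930104L06Rik 1.497, Amacr -1.42, Ndufs5 1.14, Cybrd1 0.72 and Cebpb -0.53. Elobl (1.90) lay below the array medians in all 3 genotypes and Rims2 (1.34) in control, E2f TKO and Myc KO. Both stay undecided. Cap1, 9930104L06Rik and Ndufs5 lie within 20 Mb of a deleted gene. Ndufs5 and Cybrd1 fall outside the naming rule and were named after their values were seen. Of 10092 probe sets without a single gene symbol, part of no comparison, 140 passed the test in E2f TKO, 1079 in Myc KO and 2267 in QKO against control.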

How the results depend on the processing

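The fits without the arrays labelled E2f TKO 2 and 5 and the counts without genes near the deleted genes were chosen only after the result was seen. The 9 list results with ranges below, picked to lead the report after the first fit, kept their direction and their side of the threshold in all 252 settings run on them, but no call of the 9 held with an estimated correlation (adjusted p = 0.28 to 0.926). Of 1308 settings of the other lists, 1221 kept direction and call, 84 lost the call and 3 changed sign. Of 6654 settings of single named genes, 6362 kept both, 236 lost the call, 49 gained it and 7 changed sign. Of 179 settings of the counts, 150 stayed within 1.5 times the count reported.

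Leaving out 1 array gave 277 to 830 genes for E2f TKO, 640 to 2227 for Myc KO, 3636 to 5713 for QKO, 2185 to 4288 for QKO against E2f TKO, 918 to 2008 for QKO against Myc KO and 6 to 14 for the interaction. List medians ran from 0.17 to 0.31 for G1/S and -0.46 to -0.18 for G2/M in E2f TKO, -0.64 to -0.54 for ribosome biogenesis in Myc KO, 0.40 to 0.52, -0.68 to -0.55 and -0.49 to -0.38 for the same 3 lists in QKO, -0.69 to -0.49 for ribosome biogenesis in QKO against E2f TKO, and 0.44 to 0.57 for G1/S and -0.63 to -0.47 for G2/M in QKO against Myc KO. In a fit of the 2 groups alone the counts were 253 for E2f TKO, 2681 for Myc KO and 1549 for QKO against E2f TKO. Array weights gave 1356 for E2f TKO, 3427 for Myc KO and 2265 for QKO against Myc KO. Testing every probe set gave 3014 for Myc KO, 4742 for QKO against E2f TKO and 22 for the interaction. The interaction gave 5 with only genes above the median level and 4 without genes near the deleted genes. Without the arrays labelled E2f TKO 2 and 5, E2f TKO gave 1322. The 80 genes changed the same way in E2f TKO and Myc KO became 14.5 (median of 6 assignments) with split controls, which lowers the number of controls in each fit and also ends their sharing.

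Without the arrays labelled E2f TKO 2 and 5, the list of the aryl hydrocarbon receptor response in E2f TKO had a median of 0.73, the G2/M list in the interaction 0.0282, Cyp1a1 in E2f TKO 0.75, Nqo1 0.26 and Tiparp 0.21, each the other sign of the value with all arrays. All but the G2/M list belong to the response on which these arrays were singled out, so their values there are no test. Without Myc KO 4 the interferon list in the interaction had a median of 0.0166, and without Myc KO 3 of -0.47. Without _s_at and _x_at probe sets Ctse in E2f TKO read 0.0886 and Tiparp 0.0646. With the mean of a gene's probe sets E2f1 in E2f TKO read 0.0412 and E2f2 in QKO -0.0163. For all these changes of counts, lists and genes the cause was not tested.

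With the replicate number as a block the counts were 653 for E2f TKO, 1821 for Myc KO, 5335 for QKO, 3489 for QKO against E2f TKO, 1545 for QKO against Myc KO and 11 for the interaction, and besides the calls named in the report it ended no call of a list. Whether the numbers pair the samples is open. The 25 pairs with the same number had deviations from group means that correlated at 0.10 on average (-0.16 to 0.35), other pairs at -0.03. Of 18 arrays, 6 were closest to their own number. Other pseudocounts were not tried, since the values are on a log scale. Without detection calls, changes of genes near background cannot be told from no change.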

Other observations

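The fits without the arrays labelled E2f TKO 2 and 5 were chosen only after the result was seen, and the genes of mast cells and of antigen processing were singled out after their values were seen. The mast cell protease gene Mcpt1 was lower in E2f TKO crypts (-2.06 ± 0.38, adjusted p = 0.00402), higher in Myc KO (1.46 ± 0.40, adjusted p = 0.0304) and lower in QKO (-1.85 ± 0.38, adjusted p = 0.00167), and Mcpt2 went the same ways (-2.21 ± 0.37, 1.68 ± 0.39 and -1.68 ± 0.37). The Mcpt1 call in Myc KO was lost when 1 array was left out (control 2, 3 or 4, Myc KO 1 or 2, adjusted p 0.0626 to 0.11) and in a fit of the 2 groups alone (adjusted p = 0.0673). The interaction of the pair did not pass (adjusted p = 0.734 for Mcpt1 and 0.765 for Mcpt2). Without the arrays labelled E2f TKO 2 and 5 the E2f TKO values were -1.78 and -1.74. Psmb9 and Tap1, neighbours that serve antigen processing, were lower in E2f TKO (-0.88 ± 0.12 and -1.66 ± 0.25, adjusted p = 0.000532 and 0.000812) and in QKO (-0.74 ± 0.12 and -0.71 ± 0.25, adjusted p = 0.000368 and 0.0402), while the interferon response list as a whole, which holds both genes, did not pass, with medians of -0.11 and 0.04 (camera adjusted p = 0.146 and 0.695, with a mean of -0.03 in QKO). The Tap1 call in QKO was lost when 1 array was left out (control 1, 2, 3 or 4, QKO 3, 4 or 5, adjusted p 0.056 to 0.0943), after quantile normalization (adjusted p = 0.0881), in a fit of the 2 groups alone (adjusted p = 0.0549) and with Xist as a covariate (adjusted p = 0.0621).

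Other lists did not pass against control with all arrays. Paneth cell genes had medians of 0.01 in E2f TKO, 0.08 in Myc KO and 0.14 in QKO (camera adjusted p = 0.918, 0.319 and 0.471, with 0, 0 and 1 higher and 0, 0 and 1 lower), and a mean of -0.11 in E2f TKO. Goblet cell genes had medians of 0.05 in E2f TKO, 0.14 in Myc KO and 0.17 in QKO (camera adjusted p = 0.656, 0.331 and 0.316, with 0, 0 and 2 higher and 0, 0 and 1 lower). Enterocyte genes had medians of 0.08 in E2f TKO, 0.08 in Myc KO and -0.03 in QKO (camera adjusted p = 0.258, 0.426 and 0.731, with 2, 0 and 3 higher and 0, 0 and 1 lower), and Mep1a rose in E2f TKO (1.65 ± 0.29) and QKO (1.77 ± 0.29), where Enpep (-1.03 ± 0.29) fell. The Mep1a call in E2f TKO was lost in a fit of the 2 groups alone (adjusted p = 0.0636). Genes of cholesterol synthesis had medians of -0.08 in E2f TKO, -0.26 in Myc KO and -0.14 in QKO (camera adjusted p = 0.878, 0.0524 and 0.387, with 1, 0 and 2 higher and 0, 1 and 3 lower), and immediate early and heat shock genes of 0.12 in E2f TKO, 0.14 in Myc KO and 0.25 in QKO (camera adjusted p = 0.272, 0.476 and 0.169, with 0, 1 and 3 higher and 0, 0 and 0 lower), with Egr1 (1.45 ± 0.26, adjusted p = 0.000698) and Ier3 (1.26 ± 0.29) higher in QKO. The E2f, Rb and Myc family had medians of -0.04 in E2f TKO, -0.05 in Myc KO and -0.18 in QKO (camera adjusted p = 0.502, 0.282 and 0.0726, with 0, 0 and 1 higher and 1, 2 and 6 lower), and CDK inhibitors and G1 cyclins of 0.17 in E2f TKO, 0.08 in Myc KO and 0.01 in QKO (camera adjusted p = 0.791, 0.85 and 0.766, with 1, 2 and 3 higher and 2, 1 and 3 lower), where the mean in E2f TKO was -0.16 and in QKO -0.10.

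Lists of cells outside the epithelium did not pass either, apart from endothelium in QKO. B and plasma cell genes had medians of -0.13 in E2f TKO, 0.25 in Myc KO and 0.03 in QKO (camera adjusted p = 0.656, 0.282 and 0.87, with 0, 0 and 1 higher and 0, 0 and 0 lower). Myeloid genes had medians of -0.02 in E2f TKO, 0.03 in Myc KO and 0.13 in QKO (camera adjusted p = 0.93, 0.465 and 0.717, with 0, 1 and 1 higher and 0, 0 and 0 lower), and Itgax rose in Myc KO (0.70 ± 0.16) and QKO (0.69 ± 0.15). The Itgax call in Myc KO was lost without control 4 (adjusted p = 0.051). T cell genes had medians of 0.21 in E2f TKO, 0.46 in Myc KO and 0.26 in QKO (camera adjusted p = 0.258, 0.123 and 0.609, with 0, 0 and 1 higher and 0, 0 and 0 lower), and that in Myc KO passed without the arrays labelled E2f TKO 2 and 5, at 0.46 (adjusted p = 0.0413, and adjusted p = 0.857 with an estimated correlation). Fibroblast genes had medians of 0.36 in E2f TKO, 0.12 in Myc KO and 0.14 in QKO (camera adjusted p = 0.0755, 0.259 and 0.316, with 0, 0 and 2 higher and 0, 0 and 0 lower), and smooth muscle genes of -0.01 in E2f TKO, -0.03 in Myc KO and 0.02 in QKO (camera adjusted p = 0.707, 0.945 and 0.87, with 0, 0 and 2 higher and 0, 0 and 1 lower). Genes of enteric neurons and glia had medians of 0.05 in E2f TKO, 0.07 in Myc KO and 0.11 in QKO (camera adjusted p = 0.0536, 0.259 and 0.0726, with 1, 0 and 1 higher and 0, 0 and 0 lower), and S100b rose in QKO (0.98 ± 0.11).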
